A study of Mus musculus with 12 samples.

How the data were processed

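RNA was sequenced from CD4+ T cells of gonadectomized SJL mice of a model that separates sex chromosomes from gonad type. In this model the Y chromosome lacks the testis-determining gene Sry (written Y-), and some mice carry Sry as a transgene on an autosome. Per the labels, gonads were removed at 4 to 6 weeks of age and lymph nodes were taken at 8 to 12 weeks. The cells were isolated with a magnetic kit that removes other cell types and were stimulated with anti-CD3/CD28 beads for 36 hours. The 12 libraries form 4 groups of 3, XX, XY-, XXSry and XY-Sry, taken from the sample labels. Whether each library came from a separate animal is not given in the sources used here, so p-values measure the spread between these libraries, which may be partly technical. No day, batch or lane was given in the sources used here.

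The deposited table held raw read counts per Ensembl mouse gene, with 1 column per library, per the file headers and the values, which were whole numbers. Base calls were converted with bcl2fastq 2.17 and the genome build was mm10, per the submitters' processing notes. The aligner, the counting program, the annotation release and the strand setting were not given in the sources used here. Reads from overlapping genes on opposite strands therefore could not be told apart. Of 39017 gene identifiers, 37693 matched GENCODE M21 (mm10), which supplied symbols, positions and biotypes. The 1324 unmatched identifiers held 0.597% of all counts and stayed in the tests without a symbol.

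Total counts per library ran from 11664186 to 16710188. Ratios of summed counts carry 95% intervals, and where a group had 0 counts a floor of 3 counts over the group gave a lower bound of the fold. These intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates of a group differed by more than sampling noise in all 12 pairs of libraries within groups (chi-square per degree of freedom 2.47 to 18.0 over genes with at least 20 counts), so each library was counted once.

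Differences between groups were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts: TMM factors, filterByExpr by group (minimum count 10, minimum total count 15), a model with 1 term per group over all 12 libraries, and the quasi-likelihood F-test. The filter left 14585 genes, of which 13777 were autosomal, 548 on X, 6 on Y and 226 unmatched. P-values were adjusted by Benjamini-Hochberg within a comparison, and a gene was called at an adjusted p under 0.05. The 7 comparisons were XX against XY-, XXSry against XY-Sry, the mean of both, Sry against no Sry within XX, within XY- and as their mean, and the interaction of sex chromosomes with Sry. Log2 fold changes are given with standard errors, and levels as CPM (counts scaled by library size and TMM factor), mean and SD over 3 libraries.

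Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01, adjusted over 33 lists within a comparison, and again with an estimated correlation and with fry. The lists were Y-linked genes, X-inactivation centre RNAs, X genes known to escape X inactivation, the distal X block from Tmsb4x to Mid1, X-linked immune genes, T cell activation, cytokines and chemokines, Th1, Th2, Th17, regulatory T cell, follicular helper T cell, naive and quiescent T cell, type I interferon response, interferon gamma response, NF-kB targets, immediate early genes, cell cycle, glycolysis and hypoxia, cholesterol synthesis, amino acid and integrated stress response, unfolded protein response, heat shock, p53 targets, steroid hormone receptors, cytosolic ribosomal proteins, mitochondrially encoded genes, and markers of other cells that the isolation can leave (B cell, myeloid and dendritic cell, CD8 T and NK cell, gamma delta and NKT cell, stroma and endothelium, erythrocyte and platelet). Fisher's exact test compared called with tested genes per chromosome. X genes outside the first 4 lists, and without the transcripts that overlap Xist and Gm2223, were set against autosomal genes with camera, adjusted over the 3 sex chromosome comparisons. An exact permutation test of the library means of these X genes minus those of autosomal genes was added after the results were seen.

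The groups, comparisons, tests, filters, gene lists, most alternative settings and the rule for named genes were fixed before the data were examined. By that rule the text may name every tested member of the first 4 lists, the 10 called genes with the largest fold change per comparison (average log2 CPM of at least 1, no overlap between groups), and up to 4 members of each other list that was called or had a called member. Other genes named are said to be chosen after their values were seen.

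The alternative settings were DESeq2 size factors in edgeR, no filter (at least 1 read), a mean of at least 50 reads, DESeq2 1.42.0 in place of edgeR, a block for the replicate number, only the 2 groups compared, and leaving out each library. An exact permutation test of library means of each list (400 arrangements, labels exchanged within a stratum), an offset for GC content and transcript length, an adjustment over autosomal genes alone, and the sums of X and Y gene copies were added after the data were examined. Other splits of the samples were refitted for every count. All 10 were run for 3 against 3 libraries, and 100 of 200 distinct splits (seed 11) for the others. The pseudogene Gm2223 was matched to transcripts with BLAST+ 2.17.0.

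The tests were tried on simulated counts for the 14585 genes with known changes, 50 genes at each of 1.25-, 1.5-, 2- and 4-fold. Genes were drawn independently, with a spread that followed the trend with level and not each gene's own spread. In the comparison of XX with XY-, 36.0% of genes changed 1.25-fold were recovered, 68.0% at 1.5-fold and 86.0% at 2-fold, and 4.00% of calls were false. For Sry as a mean, recovery was 42.0%, 80.0% and 96.0%, and 7.56% of calls were false. No deposited column was left out. Some results are not reported here.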

Results

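The data are gene counts from 12 libraries of stimulated CD4+ T cells, with 3 libraries in each of the groups XX, XY-, XXSry and XY-Sry. The series is about effects of the sex chromosomes in healthy cells, and its design text names the gonadal females, XX and XY-. The Sry-carrying groups, here called gonadal males because Sry directs testis development, allow the same sex chromosome comparison in the other gonad type. Total counts were 16151389, 15647796 and 11664186 in XX, 14468705, 13816220 and 15917143 in XY-, 13874970, 15610648 and 16243434 in XXSry, and 16710188, 15363551 and 13426538 in XY-Sry. XX replicate 3 stood apart, with the lowest total and 5.01% of its counts in mitochondrial genes, against 2.27% to 2.87% in the other 11 libraries. The first 3 principal components held 28.8%, 17.3% and 11.8% of the variance. On the first, every XX library lay below every XY- library, and every XXSry library below every XY-Sry library. On the second, every Sry-carrying library lay below every library without Sry of the same sex chromosome type. X and Y genes were part of these components, and no test was made of them.

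Genes that mark the sex chromosomes separated the libraries by their labels. Xist, the RNA that coats the inactive X chromosome (X, 103460366 to 103483254, mm10), had 142558 counts over the 3 XX libraries and 173 over XY-, a ratio of 852 (734 to 995). In XXSry and XY-Sry it had 131401 and 143 counts, a ratio of 920 (781 to 1092). The Y-linked genes went the other way: Ddx3y, an RNA helicase, had 4671 counts in XY- and 2 in XX, a ratio of 2259 (625 to 18660), and 4730 against 3 in the males, a ratio of 1574 (538 to 7637). Eif2s3y, Kdm5d and Uty were 1947, 1208 and 806 times higher in XY- than in XX. In the males Eif2s3y and Kdm5d were 1910 and 822 times higher in XY-Sry than in XXSry, and Uty, with 1545 counts against 0, was at least 514-fold higher. Sry itself had 5187 counts in XXSry and 0 in XX, at least 1629-fold higher, and 4556 counts in XY-Sry against 1 in XY-, a ratio of 4432 (795 to 175100). Its level was 112.8 ± 17.6 CPM in XXSry and 100.5 ± 13.9 CPM in XY-Sry (SD, n = 3), so the transgene was transcribed in these cells.

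**Figure D1:**
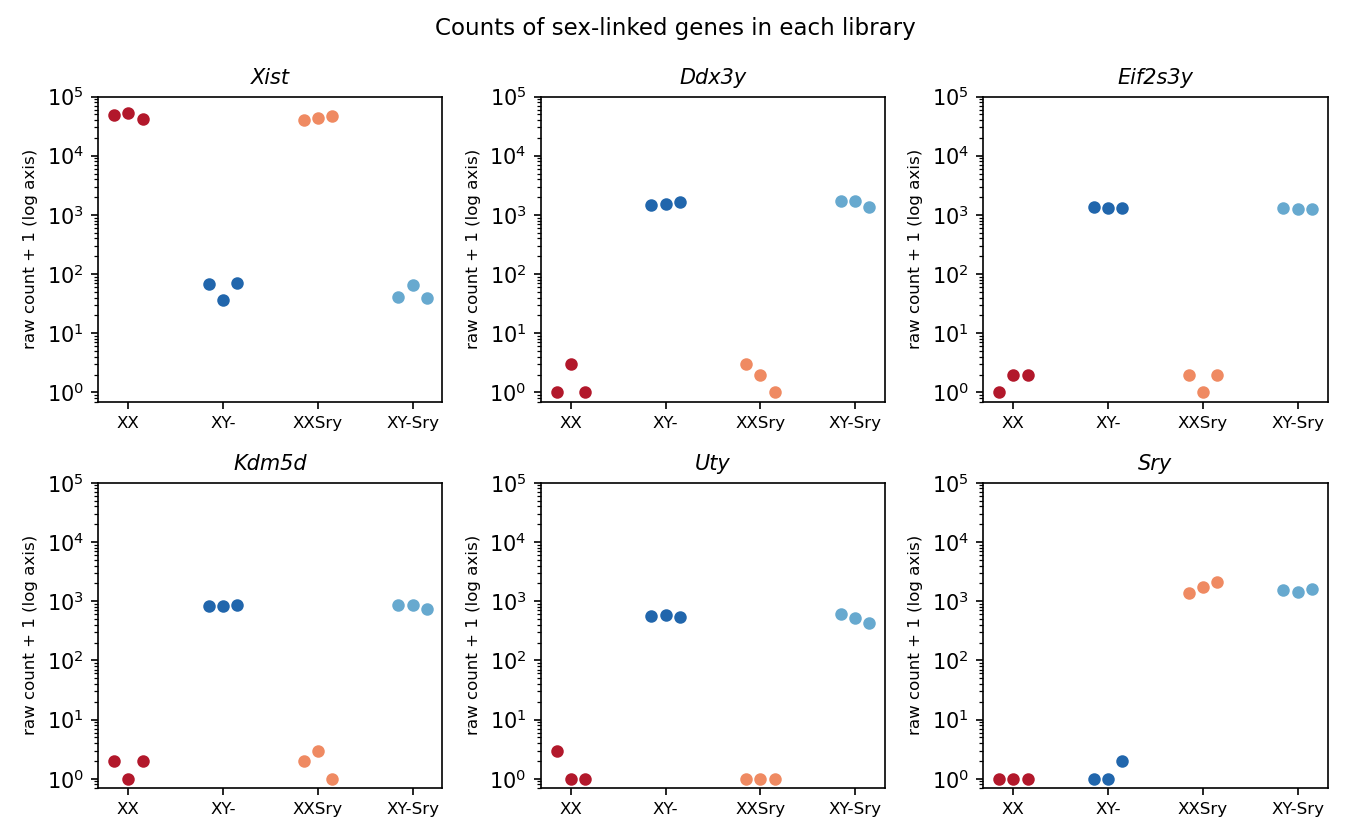
Raw counts plus 1 (log axis) of Xist, 4 Y-linked genes and Sry, with 1 point per library and 3 libraries per group. Xist was high in XX and XXSry, the Y-linked genes in XY- and XY-Sry, and Sry in both Sry-carrying groups.

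In gonadal females, XX and XY- cells differed at genes of the sex chromosomes. Genes known to escape X inactivation were higher in XX. Kdm6a, a histone H3K27 demethylase (X, 18162575 to 18279936), was at 108.7 ± 2.1 CPM in XX and 61.2 ± 3.7 in XY- (SD, n = 3), a log2 change of 0.83 ± 0.06 (edgeR adjusted p = 2.3e-06). Eif2s3x, a subunit of translation initiation factor eIF2 (X, 94188707 to 94212862), was higher by 0.68 ± 0.08 (edgeR adjusted p = 0.00082), and Kdm5c, a histone H3K4 demethylase (X, 152233020 to 152274535), by 0.41 ± 0.06 (edgeR adjusted p = 0.013). Pbdc1 (X, 105079756 to 105117090) was higher by 0.57 ± 0.08 (edgeR adjusted p = 0.0042).

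The edgeR test called 15 genes, 11 higher and 4 lower in XX. All 11 were on X and all 4 on Y (Ddx3y, Eif2s3y, Kdm5d and Uty). No autosomal gene was called by edgeR, and DESeq2 called 1. An unadjusted p under 0.05 was found for 848 autosomal genes and for 6.37% of all tested genes, where chance alone would pass a share of 0.05. Besides Xist and 4 escape genes, the X genes were Tsix, Gm26992, Gm27733, Gm27927 and Gm27520, which overlap Xist, and Gm2223. Without strand Tsix, Gm26992 and Gm27520 cannot be told apart from Xist, and Gm27733 and Gm27927 lie on its own strand. Gm2223 is a processed pseudogene whose 1350 bases are identical to Eif2s3x, so reads of these 2 genes are uncertain, and its log2 change was 0.67 ± 0.10 (edgeR adjusted p = 0.0049). Of the 8 escape genes, 4 were higher, or 6 adjusted over the list alone, and the list was called by camera with an estimated correlation (adjusted p = 0.00037). The other 4 were 5530601H04Rik at 0.49 ± 0.10, Utp14a at 0.21 ± 0.08, Ddx3x at 0.03 ± 0.09 and Car5b at -0.09 ± 0.23. The X-inactivation centre RNAs Jpx and Ftx had changes of 0.71 ± 0.18 and 0.52 ± 0.11 (edgeR adjusted p = 0.56 and 0.25). NF-kB targets (median -0.12), p53 targets (-0.18), ribosomal proteins (-0.08) and mitochondrially encoded genes (0.35) were also called by camera with its preset correlation, and none of these 4 with an estimated one (each adjusted p = 0.786). Their preset calls ended without XX replicate 3, the library high in mitochondrial counts, and those of the first 3 also without XX replicate 1, XY- replicate 1, XY- replicate 3 or XY-Sry replicate 2 (NF-kB and p53 also without XX replicate 2). Without XX replicate 2 or XY- replicate 2 the autosomal count was 2 or 3, and the Kdm5c call ended without XX replicate 1, XY- replicate 2 or XY- replicate 3 and, like that of Pbdc1, when only the 2 groups entered the fit.

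In gonadal males, XXSry and XY-Sry cells differed at nearly the same genes. Kdm6a was at 107.4 ± 6.7 CPM in XXSry and 60.7 ± 2.9 in XY-Sry (SD, n = 3), a log2 change of 0.82 ± 0.06 (edgeR adjusted p = 2.7e-06). Kdm5c was higher by 0.43 ± 0.06 (edgeR adjusted p = 0.0099) and 5530601H04Rik, a noncoding RNA (X, 105037197 to 105079609), by 0.62 ± 0.10 (edgeR adjusted p = 0.012). The only autosomal call of the edgeR test was Nrn1, which encodes neuritin, a small membrane-anchored protein, at 64.1 ± 5.3 CPM in XXSry and 43.9 ± 1.9 in XY-Sry (SD, n = 3), a log2 change of 0.55 ± 0.09 (edgeR adjusted p = 0.023). Adjusted over the 13777 autosomal genes alone, edgeR called 0 of them (lowest adjusted p = 0.33, with 1435 at an unadjusted p under 0.05, and 8 called by DESeq2 over all genes). Of all tested genes 10.4% had an unadjusted edgeR p under 0.05, above the share of 0.05 that chance alone would pass on average.

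The edgeR test called 15 genes here too, 11 higher and 4 lower in XXSry, with 10 of the higher ones on X and the same 4 Y-linked genes lower. Between the females and the males 13 calls were shared, all with the same sign, and all 15 calls of either had the same sign in the other. Of the 8 escape genes, 3 were called, or 5 adjusted over the list alone. Eif2s3x at 0.44 ± 0.08 and Pbdc1 at 0.43 ± 0.08 missed the threshold (edgeR adjusted p = 0.075 and 0.059), and the list itself was called by camera with an estimated correlation (adjusted p = 0.0012). With the preset correlation camera also called, among others, cytokines (median -0.46), p53 targets (-0.25), NF-kB targets (-0.22), T cell activation (-0.17), ribosomal proteins (-0.14), glycolysis (0.14) and naive T cell genes (0.15), and none of these 7 with an estimated one (adjusted p = 0.39 to 0.59). The T cell activation and naive T cell calls ended without XXSry replicate 3, and the glycolysis call without XY-Sry replicate 2. The call of 5530601H04Rik ended without XXSry replicate 2 or 3 or XY-Sry replicate 1 or 3, and that of Gm2223 without XXSry replicate 1 or 2 or XY-Sry replicate 2 or 3. The calls of Kdm5c and Nrn1 each ended in 5 of 12 fits that left out 1 library. Those for Kdm5c were the fits without XXSry replicate 1 or 2 or any XY-Sry library, and those for Nrn1 the fits without XXSry replicate 2 or 3 or any XY-Sry library, which left 0 autosomal calls, while the fit without XX replicate 2 had 2.

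Taken as the mean of both gonad types, the sex chromosome difference covered 20 genes, 14 higher and 6 lower in XX. It held 13 X genes, 4 Y genes and 3 autosomal genes. An unadjusted edgeR p under 0.05 was found for 2071 genes, 14.2% of those tested. That is above the share of 0.05 that chance alone would pass on average. Of the 8 escape genes 5 were higher, also adjusted over the list alone, with a list median of 0.46: Kdm6a by 0.83 ± 0.05, Eif2s3x by 0.56 ± 0.06, 5530601H04Rik by 0.55 ± 0.07, Pbdc1 by 0.50 ± 0.06 and Kdm5c by 0.42 ± 0.05 (edgeR adjusted p = 2.1e-08 to 0.00064). Jpx, an activator of Xist (X, 103493556 to 103565696), was higher by 0.70 ± 0.12 (edgeR adjusted p = 0.039). The autosomal genes were Plxna1, a semaphorin receptor, at -0.39 ± 0.07, the zinc finger gene Zbtb38 at 0.21 ± 0.04, and Rpl12, a ribosomal protein gene, at -0.33 ± 0.06 (edgeR adjusted p = 0.034, 0.034 and 0.046). Adjusted over autosomal genes alone, edgeR called 0 of them (lowest adjusted p = 0.14, with 1954 at an unadjusted p under 0.05), and DESeq2 over all genes called 64, so the 3 calls rest on the adjustment together with the X and Y genes. In 12 fits without 1 library each, the calls of Jpx, Rpl12 and Zbtb38 ended in 10 and that of Plxna1 in 9, and all 4 were kept without XY- replicate 2. Without that library the test called 91 genes, 70 of them autosomal, against 11 autosomal genes without XXSry replicate 1, 3 without XX replicate 3, 1 without XX replicate 1, XX replicate 2 or XY-Sry replicate 3, and 0 without any of the other 6.

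Several immune and growth gene lists leaned one way in this mean, and none of those given here was called with an estimated correlation or by exact permutation. Cytokine and chemokine genes had a median log2 change of -0.46 in XX against XY-, with 12 of 14 members negative, 0 called and 8 lower adjusted over the list alone. Tnf and Il2, a pair of cytokine genes of activated T cells, stood at -0.32 ± 0.07 and -0.78 ± 0.22 (edgeR adjusted p = 0.097 and 0.22). NF-kB targets had a median of -0.15 with 12 of 12 negative, p53 targets -0.23 with 8 of 10 negative, and ribosomal proteins -0.11 with 61 of 74 negative and 1 called. Genes of naive T cells had a median of 0.12 with 13 of 13 positive, and glycolysis genes 0.09. Camera with the preset correlation called these 6 lists among others (adjusted p = 0.0011, 0.0011, 0.0094, 8.6e-05, 0.012 and 0.049). With an estimated correlation none of the 6 was called (adjusted p = 0.53 to 0.78). The exact permutation test of library means called none of the 33 lists, its lowest adjusted p being 0.055 for the 3 sex chromosome lists. Those stood at its smallest possible p of 0.005, so this test had little room to call any list. Its unadjusted p was 0.045 for cytokines, 0.03 for NF-kB, 0.01 for p53, 0.015 for ribosomal, 0.045 for naive T cell and 0.13 for glycolysis genes. Of the 6 lists fry called the ribosomal proteins (adjusted p = 0.047). The glycolysis call also ended without XX replicate 1 or 2, XY- replicate 1 or 3, XXSry replicate 3 or XY-Sry replicate 2, and the naive T cell call without XXSry replicate 3.

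X genes outside the escape, X-inactivation centre and distal block lists, and without the transcripts that overlap Xist and Gm2223, showed no called shift as a class. The median log2 change of these 524 genes lay above that of autosomal genes by 0.03 in females, 0.01 in males and 0.03 in the mean. Camera in limma gave an adjusted p of 0.30, 0.46 and 0.30 with the preset correlation and of 0.15, 0.31 and 0.15 with an estimated one. A two-sided exact permutation test of the library means gave p = 0.3, 0.5 and 0.145 (adjusted p = 0.45, 0.5 and 0.435), where the smallest possible p was 0.1 in females and males and 0.005 in the mean. The X-linked immune genes had a median of 0.03 in the mean, with 0 of 16 called by edgeR. Called genes lay on X and Y beyond their share of tested genes in all 3 sex chromosome comparisons and on no autosome (Fisher's exact test per chromosome, adjusted p = 3.3e-13 for X and 4.0e-10 for Y in the mean). Y genes and Xist differ by the genotypes compared, and transcripts that overlap Xist are not independent of it. These p-values therefore add little to the called genes themselves. In the distal X block from Tmsb4x to Mid1 (X, 167207093 to 170005736), the median of 7 tested genes was 0.06 in the mean, from -0.07 for Hccs to 0.28 for Tlr7, a receptor for single-stranded RNA (edgeR adjusted p = 0.27), and 0 of 7 were called.

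**Figure D2:**
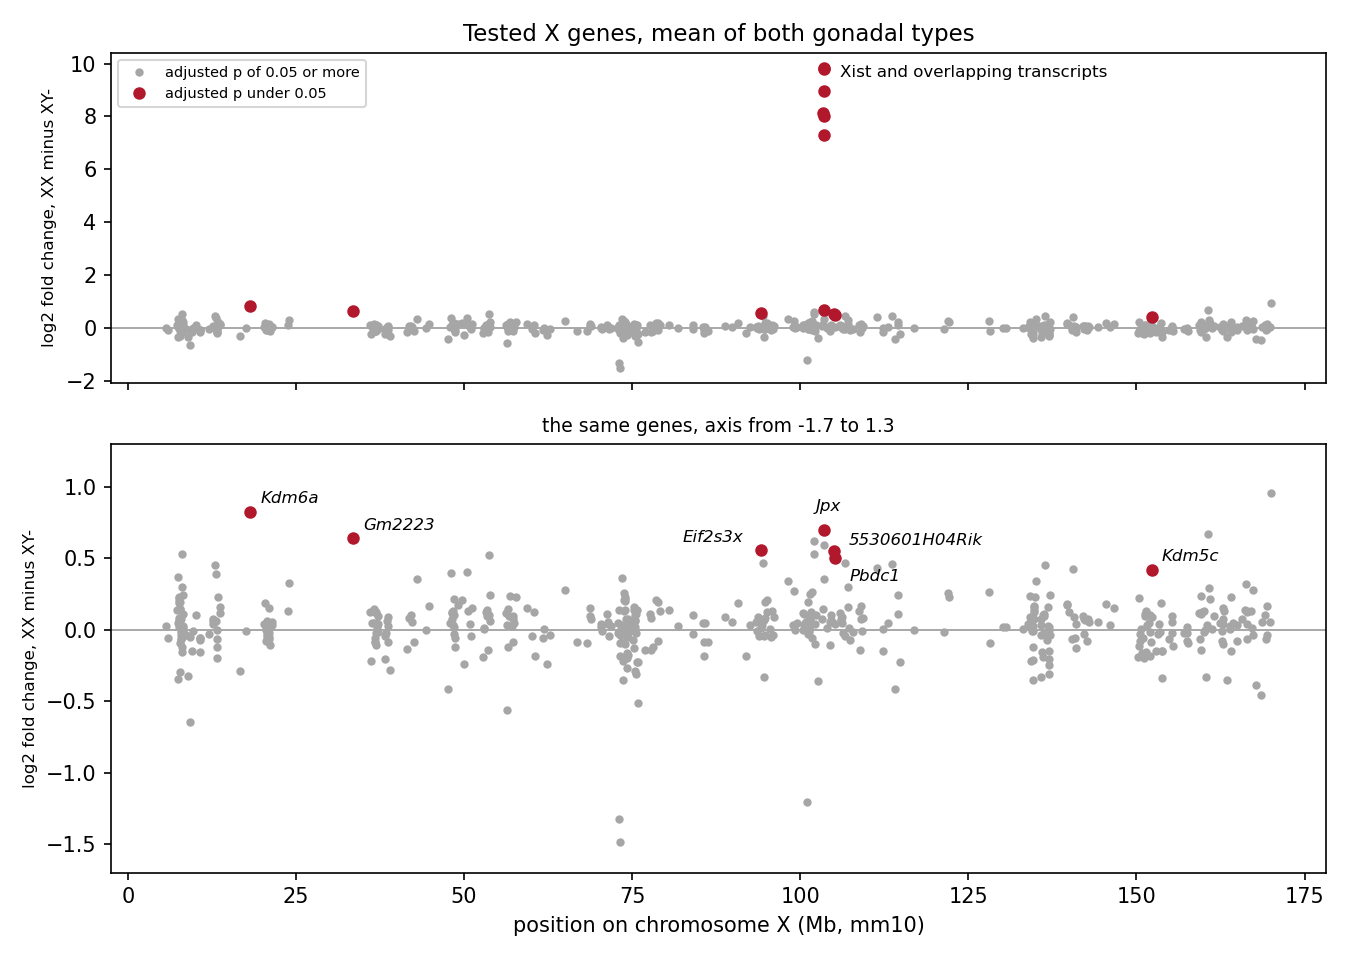
Log2 fold change of XX against XY-, mean of both gonad types, for 548 tested X genes by position in Mb (mm10), with called genes in red and the lower panel on a narrower axis. Xist and the transcripts that overlap it lie above 7 (fitted values that depend on the prior count where a group has almost no counts), and the other called genes lie between 0.42 and 0.83.

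Sry-carrying cells differed from cells without Sry in many autosomal genes. Genes induced by type I interferon were lower with Sry, with a median log2 change of -0.64. Genes of glycolysis and of the response to low oxygen were lower too, with a median of -0.27. NF-kB targets had a median of 0.24 and Th17 genes of 0.50, with 9 of 12 and 1 of 9 called higher. Camera called these 4 lists with the preset correlation and none with an estimated one (adjusted p = 0.12 to 0.21), and exact permutation called all 4 (adjusted p = 0.0275). Gonad type before gonadectomy and the transgene itself go together in this comparison, which therefore covers both.

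The mean of both sex chromosome types held 793 genes by edgeR, 310 higher and 483 lower with Sry, of which 766 were autosomal. Their median size was 0.35 on the log2 scale, and 57 changed more than 2-fold. The largest changes under the rule were in genes at modest levels. Dapl1, a gene of naive T cells, was at 19.9 ± 3.4 CPM in XX, 20.1 ± 0.8 in XY-, 7.54 ± 3.02 in XXSry and 5.72 ± 0.96 in XY-Sry (SD, n = 3), a log2 change of -1.60 ± 0.15 (edgeR adjusted p = 8.4e-05). Akr1c18, which encodes 20-alpha-hydroxysteroid dehydrogenase, fell by 1.82 ± 0.31 on the log2 scale, F2rl1, a receptor cleaved by proteases, fell by 1.51 ± 0.25, and Vldlr, a lipoprotein receptor, fell by 1.18 ± 0.20. Higher were the chemokine receptor gene Ccr9 by 1.26 ± 0.27, the adhesion gene Mcam by 1.21 ± 0.12 and Nqo1, a quinone reductase, by 1.20 ± 0.14 (edgeR adjusted p of these 6 = 0.00016 to 0.014). Leaving out 1 library moved the count over 1.5 times in 6 cases: 358 without XY-Sry replicate 1, 370 without XXSry replicate 2, 402 without XY-Sry replicate 2, 427 without XY- replicate 2, 433 without XXSry replicate 1 and 1282 without XXSry replicate 3. No called gene changed sign in the 12 fits without 1 library, and 353 to 751 of the 793 remained called.

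Type I interferon genes held the highest number of called genes among the lists. Of 29 tested members, 19 were lower, or 25 lower and 1 higher adjusted over the list alone. Mx2, an antiviral GTPase, fell from 12.6 ± 1.8 CPM in XX and 11.3 ± 4.2 in XY- to 6.21 ± 1.96 in XXSry and 5.66 ± 1.26 in XY-Sry (SD, n = 3), and Isg20, an RNA exonuclease, had a log2 change of -0.77 ± 0.13 (edgeR adjusted p = 0.0068 and 0.0047). Rtp4 and Ifit2 changed by -0.89 ± 0.17 and -0.25 ± 0.05. Camera called the list with the preset correlation (adjusted p = 4.2e-21), not with an estimated one (adjusted p = 0.21), and the exact permutation test gave 0.005, the smallest of its 400 arrangements (adjusted p = 0.0275). Libraries varied: XXSry replicate 3 had a centred list mean of 0.14, above XY- replicate 3 at -0.08. Genes of the interferon gamma response had a median of 0.12, with 0 of 16 called and 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.015 preset and 0.33 with an estimated correlation).

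Some metabolic genes were lower with Sry. Of 20 glycolysis and hypoxia genes 15 were lower, or 17 adjusted over the list alone: Egln3, an oxygen-sensing prolyl hydroxylase, at -0.78 ± 0.09, the glucose transporter Slc2a1 at -0.46 ± 0.06, and the glycolytic enzymes Tpi1 at -0.32 ± 0.05 and Pfkp at -0.30 ± 0.05 (edgeR adjusted p = 0.00038 to 0.0044). In cholesterol synthesis 5 of 19 genes were lower, or 7 adjusted over the list alone, among them Lss, lanosterol synthase, at -0.32 ± 0.04, with a list median of -0.09. In the amino acid and integrated stress response 4 of 15 were lower, or 8 adjusted over the list alone, such as the transcription factor Ddit3 at -0.40 ± 0.07, with a median of -0.13. Mitochondrially encoded genes had a median of -0.35 with 23 of 23 negative and 3 called (14 adjusted over the list alone), such as the 16S ribosomal RNA mt-Rnr2 at -0.40 ± 0.10. That median was -0.19 without XX replicate 3, the library with the highest mitochondrial share, and the mt-Rnr2 call ended without XY- replicate 2 or 3, XXSry replicate 1 or 2 or XY-Sry replicate 1 or 2. Camera adjusted p was 9.2e-19, 1.3e-05, 3.7e-05 and 8.5e-07 for these 4 lists with the preset correlation and 0.12, 0.13, 0.25 and 0.25 with an estimated one. Exact permutation gave an adjusted p of 0.0275, 0.0495, 0.0413 and 0.0688. In the unfolded protein response 3 of 11 genes were lower, led by the transcription factor Xbp1 at -0.41 ± 0.05, and the list was not called (adjusted p = 0.098).

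Genes downstream of T cell receptor and NF-kB signalling were higher with Sry in part. Of 12 NF-kB targets 9 were higher, or 10 adjusted over the list alone, among them the NF-kB subunit genes Nfkb2 by 0.46 ± 0.09, Relb by 0.46 ± 0.09 and Nfkb1 by 0.25 ± 0.05 (edgeR adjusted p = 0.0084, 0.010 and 0.0071). In the T cell activation list 6 of 21 were higher and 2 lower, or 7 and 2 adjusted over the list alone. Nr4a1, an early gene of receptor signalling, was higher by 0.76 ± 0.09, and the inhibitory receptor genes Pdcd1 and Lag3 by 0.66 ± 0.10 and 0.36 ± 0.07, while the transferrin receptor gene Tfrc and the IL-2 receptor gene Il2ra were at -0.29 ± 0.05 and -0.18 ± 0.04 (edgeR adjusted p = 0.00049 to 0.020). Of 11 immediate early genes 3 were higher, among them Junb by 0.31 ± 0.05, and 2 of 7 heat shock genes, among them Hsph1 by 0.31 ± 0.08. Among the fits without 1 library the Hsph1 call was kept only without XX replicate 1, XY- replicate 1 or XXSry replicate 3, and the Il2ra call ended without XY- replicate 2 or 3, XXSry replicate 1 or 2 or XY-Sry replicate 2. Camera called the NF-kB, activation and heat shock lists (adjusted p = 1.1e-10, 0.0085 and 0.0085), none of them with an estimated correlation (adjusted p = 0.13, 0.40 and 0.29), and exact permutation gave an adjusted p of 0.0275, 0.0943 and 0.0495. Immediate early genes as a list were not called (adjusted p = 0.11).

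T cell subset genes moved in different directions. Of 9 Th17 genes 1 was higher, or 7 adjusted over the list alone: the chemokine receptor gene Ccr6 by 0.54 ± 0.15, with Il17f at 1.05 ± 0.30 (edgeR adjusted p = 0.044 and 0.054). The list had a camera adjusted p of 4.6e-05, of 0.12 with an estimated correlation, and of 0.0275 by exact permutation. The Ccr6 call ended in 9 of 12 fits without 1 library and was kept without XX replicate 1, XY- replicate 1 or XXSry replicate 3. Of 14 Th1 genes 4 were lower, among them Stat4, a mediator of IL-12 signalling, at -0.47 ± 0.09, and the list (median -0.17, adjusted p = 0.036, and 0.34 with an estimated correlation) was called in 6 of 12 fits without 1 library. Regulatory T cell genes were split, with Izumo1r and Gpr83 at -0.52 ± 0.08 and -0.73 ± 0.11, and Ikzf2 higher by 0.41 ± 0.06. Among naive T cell genes Tcf7 was higher by 0.32 ± 0.05 and Dapl1 lower, and of Th2 genes Ccr8 was higher by 0.78 ± 0.13 and Nfil3 lower at -0.52 ± 0.07. These 3 lists and the follicular helper list, with Pdcd1 as its called gene, were not called by camera (adjusted p = 0.21, 0.33, 0.40 and 0.21), although exact permutation called the follicular helper list (adjusted p = 0.0275). Cytokine genes had a median of 0.33 with 0 of 14 called (camera adjusted p = 0.028, 3 of 12 fits without 1 library, and 0.48 with an estimated correlation), and p53 targets 0.10 with 1 of 10 called (adjusted p = 0.022, and 0.34 with an estimated correlation).

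Markers of other cell types were mostly at low levels. In the CD8 T and NK cell list 2 of 5 tested genes were lower with Sry: Cd8a, a CD8 subunit, at 3.67 ± 1.14 CPM in XX, 5.17 ± 1.32 in XY-, 1.87 ± 0.40 in XXSry and 2.13 ± 0.33 in XY-Sry, and Klrk1, a receptor of killer cells, whose call ended without XY-Sry replicate 1. The list was not called by camera (adjusted p = 0.059) but was by exact permutation (adjusted p = 0.0413). Cd8b1, the other CD8 subunit, had a log2 change of 0.15 ± 0.07 (edgeR adjusted p = 0.24). Of 10 B cell genes 1 was higher, Cd74 by 0.34 ± 0.08, whose call ended without XY- replicate 2, XXSry replicate 1 or 2 or XY-Sry replicate 2 or 3. None of 4 myeloid, 2 gamma delta and NKT, 3 stromal and 1 erythrocyte genes was called by edgeR. The same held for 34 cell cycle genes, 4 X-inactivation centre RNAs, 8 escape genes and 7 genes of the distal X block, while 1 of 74 ribosomal genes was lower and 1 of 16 X-linked immune genes, Itm2a, was higher by 0.50 ± 0.07. Of the 793 genes 44 lay on chromosome 3, which carries the transgene in this model, 5.55% of calls against 4.46% of tested genes (odds ratio 1.28, 0.909 to 1.75, Fisher's exact test, adjusted p = 0.38).

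**Figure D3:**
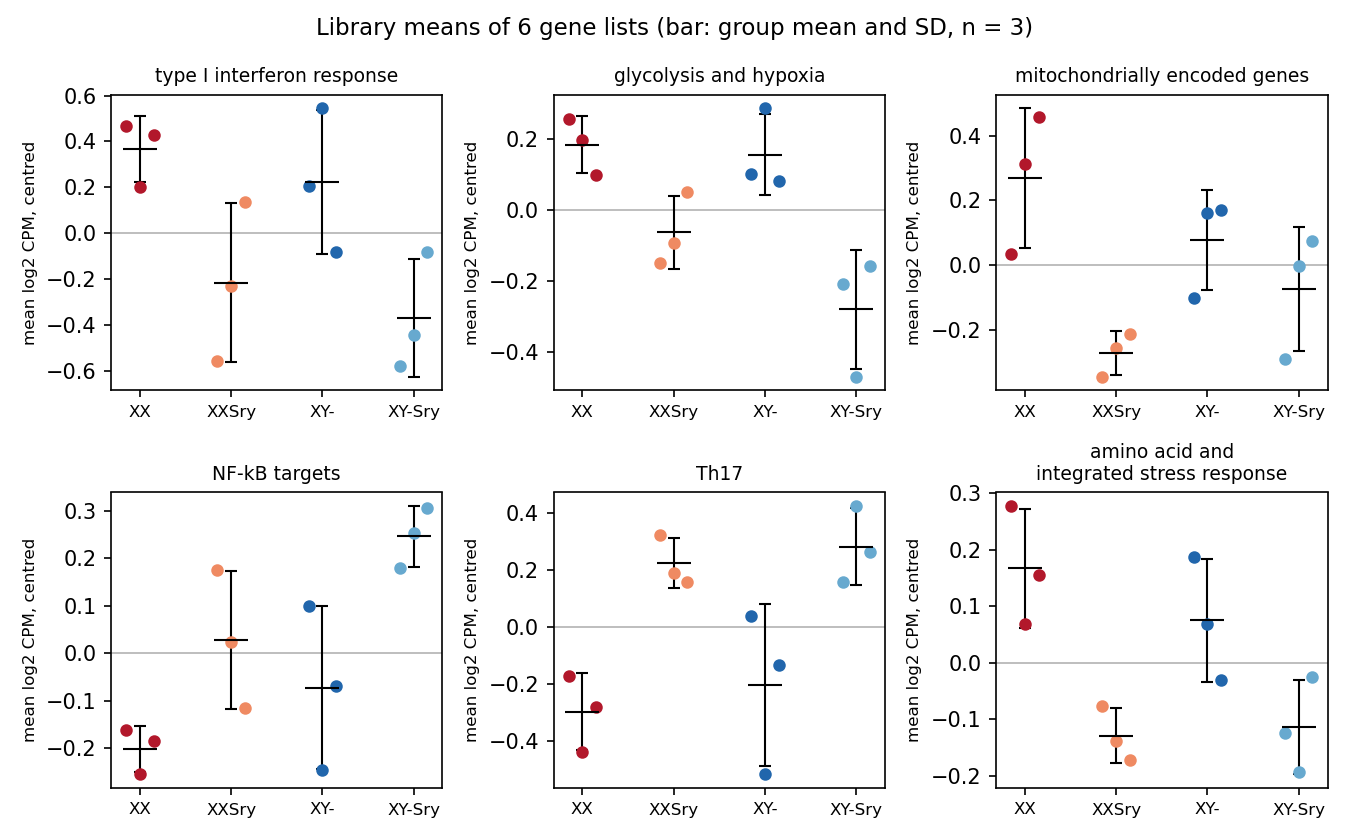
Mean log2 CPM of the tested members of 6 gene lists in each library, centred on the mean over the libraries, with 1 point per library, and a bar and whiskers for the group mean and SD (n = 3). Type I interferon, glycolysis, mitochondrial and stress response genes lie lower in the Sry-carrying groups on average, and NF-kB and Th17 genes higher.

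Within XX alone, Sry-carrying cells had lower Dapl1 (log2 change -1.37 ± 0.21), Xdh, which encodes xanthine dehydrogenase (-0.91 ± 0.11), and Tgm2, a transglutaminase (-1.02 ± 0.16), and higher Mcam (1.22 ± 0.18) (edgeR adjusted p = 0.0027 to 0.016). The edgeR test called 66 genes, 29 higher and 37 lower. Within XY-, Dapl1 fell by 1.82 ± 0.21, the Wnt receptor gene Fzd7 fell by 1.38 ± 0.19 and the metallothionein gene Mt1 fell by 1.32 ± 0.26 on the log2 scale, and Nqo1 was higher by 1.64 ± 0.20 (edgeR adjusted p = 0.0017 to 0.033). Here 99 genes were called, 16 higher and 83 lower. The comparisons shared 34 calls, all with the same sign. Of 29 interferon genes 0 were called in either, 19 and 22 were lower adjusted over the list alone, and the median was -0.64 in both. Glycolysis genes had medians of -0.19 and -0.32 and NF-kB targets 0.20 and 0.28. Camera called these 3 lists in both with the preset correlation, and with an estimated one only the Y-linked list, which holds Sry (the 3 lists had an adjusted p of 0.26 each within XX, and of 0.24, 0.071 and 0.14 within XY-).

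The counts within XX and within XY- rested on single libraries. Within XX the count was 2 without XXSry replicate 2, 6 without XXSry replicate 1, 14 without XX replicate 1, 17 without XX replicate 3, 25 without XY-Sry replicate 2, 28 without XY- replicate 3, 43 without XY-Sry replicate 3, 120 without XY- replicate 2, 144 without XXSry replicate 3 and 146 without XX replicate 2, and it was 4 when only the 2 groups entered the fit. Within XY- it was 8 without XY-Sry replicate 2, 12 without XY- replicate 2, 14 without XY-Sry replicate 1, 26 without XXSry replicate 2, 29 without XY-Sry replicate 3, 39 without XY- replicate 3, 181 without XY- replicate 1 and 182 without XXSry replicate 3, and 278 with only the 2 groups. Within XX the Dapl1 call ended without XX replicate 3 or XXSry replicate 2, that of Mcam without XXSry replicate 1 or 2, and that of Tgm2 without XX replicate 1 or 3 or XXSry replicate 1 or 2, and all 3 ended when only the 2 groups entered the fit. Within XY- the Fzd7 call ended without XY-Sry replicate 2, and that of Mt1 without XY- replicate 2 or 3, XXSry replicate 2 or any XY-Sry library.

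The interaction asked whether the sex chromosome difference depended on gonad type. It gave 0 genes by edgeR and 0 by DESeq2. At an unadjusted p under 0.05 there were 385 genes, 2.64% of those tested, fewer than that threshold would pass by chance. Nrn1, called in males, and Eif2s3x and Pbdc1, called in females, were therefore not shown to differ between gonad types. Camera with the preset correlation called glycolysis, cholesterol synthesis, ribosomal and mitochondrial genes, and none of the 4 with an estimated correlation (adjusted p = 0.533).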

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

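All tests of explanations in this part were chosen after the results were seen. The sex chromosome difference was compared between gonad types by the interaction, as the change in females minus that in males, and 4 gene lists differed there by camera with the preset correlation. Glycolysis and hypoxia genes had a median interaction of -0.12 (adjusted p = 0.00017), cholesterol synthesis genes -0.0727 (adjusted p = 0.0050), ribosomal proteins 0.0557 (adjusted p = 0.0060) and mitochondrially encoded genes 0.41 (adjusted p = 6.5e-09). With an estimated correlation all 4 had an adjusted p of 0.533, and 82 of 100 splits of the samples gave 4 or more lists (up to 15), so that chance cannot be excluded for this number of lists.

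The mitochondrial pattern was the largest of the 4. The median of XX against XY- was 0.35 in females, and the library with the highest mitochondrial share, XX replicate 3 at 5.01%, lies in that group. Without it the median interaction was 0.13, against 0.41 with it, and the p with an estimated correlation was 0.11, against 0.035, so that most of the pattern may rest on this library. The preset test still called the list without it (adjusted p = 8.4e-05). What sets that library apart stays open, since no label gives RNA quality or a batch, and a difference of XX females as a group was not told apart from it.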

How the results depend on the processing

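The exact permutation test, the GC and length offset and the adjustment over autosomal genes alone were chosen after the data were examined, the other alternatives before. DESeq2 size factors changed no call count by over 1.5 times. With no filter on low counts (27235 genes), the counts were 124 (88 autosomal) in females, 368 (332) in males, 652 in the mean, 1494, 638 and 703 for Sry as a mean, within XX and within XY-, and 32 for the interaction. The autosomal genes differing by sex chromosomes, mean of both gonadal types, numbered 597. Nearly all of these genes were also tested with the filter (649 of 652 in the mean), and the prior degrees of freedom went from 6.79 to infinity in the same fit. With DESeq2 they were 18 (1), 25 (8), 84 (64), 973, 260 and 260, and 0. A mean of at least 50 reads gave 5 autosomal genes in the mean, the GC and length offset 0. Fits with only the 2 groups gave 4 genes for Sry within XX and 278 within XY-. Adjusted over autosomal genes alone, edgeR called 0 autosomal genes in females, males and the mean (0, 1 and 3 over all genes). What made the other counts move was not tested. With an estimated correlation camera called 3, 3 and 3 lists for the sex chromosomes (7, 11 and 10 preset), 1, 1 and 1 for Sry (14, 10 and 13) and 0 for the interaction (4), fry called 3, 3 and 5 for the sex chromosomes (females, males, mean), 9, 1 and 7 for Sry (mean, within XX, within XY-) and 0 for the interaction, and exact permutation called 0 lists for the sex chromosome mean and 10 for Sry. The Y-linked list, which holds Sry itself, was 1 of those 10.

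Leaving out 1 library gave 14 to 18 genes (0 to 3 autosomal) in females, 11 to 17 (0 to 2) in males, 16 to 91 (0 to 70) in the mean, 358 to 1282 for Sry, 2 to 146 within XX, 8 to 182 within XY- and 0 for the interaction. Lists ran from 3 to 12 in females (3 without XX replicate 3, 12 without XY- replicate 2), 11 to 13 in males, 8 to 12 in the mean, 12 to 15, 9 to 12 and 12 to 14 for Sry, and 3 to 12 for the interaction (8 without XX replicate 3, 9 without XX replicate 2, 11 without XY- replicate 1, 12 without XXSry replicate 1). Of 9054 values of 519 named gene and comparison pairs under alternatives, 8297 stayed on the same side of the threshold, 426 lost and 324 gained a call, 0 changed direction and 7 had no adjusted p. Of 162 called pairs 90 were kept in all.

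The replicate numbers did not pair the samples consistently, and partial sharing by number was not ruled out. Deviations of 18 same-numbered pairs correlated at -0.16 to 0.23, 5 of them over 0.1, and 3 of 12 libraries correlated best with their own number. With the replicate block the counts were 16, 15 and 28 (10 autosomal) for the sex chromosomes, against 15, 15 and 20 without it. For Sry they were 944, 103 and 109, against 793, 66 and 99, and for the interaction 0 in both. The simulation recovered 68.0% of genes changed 1.5-fold in the comparison of XX with XY-. It held 150 calls, against 15 in the data, which eases the adjustment, and gave each gene only the trended spread. Recovery in the data may thus be lower.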

Other observations

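All tests in this part were chosen after the results were seen, except the GC and length offset, whose bounds were written before its result, and the comparison of chromosomes, which was planned.

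Genes with a copy on both X and Y showed how far the Y copy went with the single X in XY- cells. Summed over both copies, Ddx3 was at 493 ± 41 CPM in XX, 587 ± 41 in XY-, 517 ± 56 in XXSry and 635 ± 27 in XY-Sry (SD, n = 3). All ratios here set XX against XY- as the mean of both gonad types on the log2 scale. For Ddx3 the ratio was 0.825 (0.740 to 0.919). Eif2s3, with its pseudogene Gm2223, had a ratio of 0.702 (0.641 to 0.769), Kdm6 (Kdm6a with Uty) 1.12 (1.05 to 1.19) and Kdm5 1.04 (0.970 to 1.12). The Y copy held 17.9% of Ddx3, 56.6% of Eif2s3, 38.1% of Kdm6 and 22.5% of Kdm5 counts in XY-. Gm2223 is identical to part of Eif2s3x, and how reads shared by these genes were counted is not known. The ratio and Y share of Eif2s3 carry that uncertainty beyond the interval. Sums that were equal in every pair could be expected if the Y copy replaced the missing X copy, and 3 of 4 pairs differed (exact permutation p = 0.005, the smallest of 400 arrangements, adjusted p = 0.00667; Kdm5 p = 0.195), which argues against equal sums as a rule. In XX 0.00863% to 0.0458% of a pair's counts fell on the Y copy, so few X reads were counted there, and per kilobase of transcript the ratios were 0.822 for Ddx3, 0.642 for Eif2s3, 1.09 for Kdm5 and 1.06 for Kdm6 (exact permutation p = 0.005, 0.005, 0.03 and 0.045, unadjusted). Whether Kdm5 differed thus depends on whether transcript length is counted.

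Log2 changes correlated across 13777 autosomal genes, which are not independent replicates. Between XX and XY- cells the Sry changes had r = 0.47, above the other label exchanges (highest 0.42, exact permutation p = 0.005 one-sided, the smallest possible), consistent with a Sry response shared by both. The sex chromosome changes in females and males had r = 0.24, reached by 20 of 400 exchanges (highest other 0.39, exact permutation p = 0.05 one-sided), and whether they share an autosomal response cannot be told apart from chance at this number of libraries.

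The Sry difference was the largest pattern by number of called genes, and 3 technical explanations were set against it. After an offset for GC content and transcript length 830 genes were called, 749 of them among the 793, which argues against such a bias as its cause. Genes carried along with the transgene, as the source of most calls, would crowd chromosome 3, and it held 5.55% of the calls against 4.46% of tested genes. Genes near the insertion were not examined, so such an effect on some of the 44 calls there stays open. More CD8 T cells in the libraries without Sry, which the isolation should remove, could account for Cd8a, but Cd8b1 changed by 0.15 (-0.00036 to 0.31), against -1.11 (-1.50 to -0.72) for Cd8a, and the same fall of 2.42 CPM in Cd8b1 would be -0.36. Klrk1 at -1.34 (-1.97 to -0.71) and the call of the CD8 T and NK cell list by exact permutation (adjusted p = 0.0413) go with such cells. Klrd1 at -0.08 (-0.76 to 0.61) and Prf1 at -0.12 (-0.92 to 0.69), both at low levels, do not. If such cells carry as much Cd8b1 as Cd8a, which was not measured, Cd8b1 argues against them as the source of the Cd8a change. The fall of Klrk1 stays open. The transgene, gonadal hormones before gonadectomy and unlabelled differences in housing or handling stay open.

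An extra copy of the block on the Y chromosome could give XY- cells 2 active copies of the distal X genes, against 1 in XX where 1 X is silent (a log2 change of -1) or 2 where both are active (0). In the mean 7 of 7 tested genes had an interval above -1, and 1 of 7, Tlr7 at 0.28 (0.07 to 0.49), excluded both values. For these 7 genes the intervals argue against an extra copy with 1 X of XX silent. An extra copy with both X active cannot be told apart from no extra copy. How active these genes are on the second X was not measured here.

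Other splits of the same samples were refitted. For the sex chromosome mean 1 of 100 splits, the real one, gave as many as 20 genes (highest other 0). This decides nothing on chance for the 20 genes, because 13 lie on X and 4 on Y. Other splits mix the sex chromosome types or set them against each other, so such genes had little way to be called there. At least 10 lists came from 25 of 100 splits (highest other 15), so chance cannot be excluded for their number. As many as 3 autosomal genes were called in 1 of 100 splits (highest other 0), which decides nothing, because other splits lack the X and Y calls that eased the adjustment, and 0 were called over autosomal genes alone. For Sry 2 of 100 splits gave at least 793 genes (highest other 928) and 2 of 100 gave at least 14 lists (15), each a share under 0.05, a bound written after the results. The lists tested include the Y-linked one, which holds Sry, and a split that mixes Sry has little way to call it. Since some other splits reached 13 lists, the share for lists decides little. The split with 928 genes exchanged XX replicate 1 with XXSry replicate 3, and Sry had 0 counts in XX replicate 1, which argues against a swap of these libraries. All other libraries stayed together by Sry in that split, with the 2 sides named the other way round. Its medians were 0.40 for interferon genes, -0.21 for NF-kB targets and 0.18 for glycolysis genes, the Sry pattern with reversed sign. A split that followed Sry in most libraries thus gave more genes than Sry itself, and its count does not show a pattern apart from Sry. A difference between libraries other than Sry stays open. For the interaction the count was 0 genes, which 100 of 100 splits reach by definition, so they say nothing on it. The highest other count was 555, in a single split. Its medians on the interaction scale were 0.33 for NF-kB targets, -0.19 for glycolysis genes and -0.64 for interferon genes. That scale is 2 times as wide as that of the Sry mean, so the sizes cannot be compared directly. These signs are those seen with Sry, while each side of that contrast held as many libraries with Sry as without. These lists thus also varied among libraries apart from Sry, and why was not tested. At least 4 lists came from 82 of 100 splits (15), so chance cannot be excluded for their number. With 3 against 3 libraries only 10 splits exist, too few for a share under 0.05. There the real and highest other counts were 15 and 0 in females (reached by 1 of 10), 15 and 0 in males (1), 66 and 4 for Sry within XX (1) and 99 and 0 within XY- (1). In females and males the other splits again mix the sex chromosome types, so those counts decide nothing. Autosomal counts were 0 and 0 in females (10 of 10) and 1 and 0 in males (1), and list counts 7 and 15 (5), 11 and 9 (1), 10 and 8 (1) and 13 and 13 (2) in the same order as the genes.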
